A study of Mus musculus with 8 samples.

How the data were processed

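Liver RNA from C57BL/6 mice was measured by sequencing in 8 libraries. Per the labels the mice were 14 to 16 days old, an age given for tumor and normal liver alike and not checked here. They were wild type or carried a hepatocyte deletion of Nfib made with Alb-Cre, and gave tumor or normal liver. RNA was isolated with mirVana, had an integrity number of 7 or more, and went into stranded TruSeq mRNA libraries. The libraries were grouped as 3 wild-type tumors, 2 wild-type normal livers, 2 knockout tumors and 1 knockout normal liver. The replicate number in each name was kept as given. The labels do not state that equal numbers come from 1 animal, so no pairing entered the reported tests. The names wild type and knockout are those of the labels throughout.

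The deposited count table holds raw counts per gene for 21878 genes. Counts were whole numbers, and totals ran from 11912549 to 19965842 per library. The deposited FPKM table holds FPKM values made by the authors, whose formula is not stated. It was used for alternatives. Per the labels the upstream processing involved Bowtie 0.12.2 and the genome builds mm8 and mm9, with no role given for either build, and the counting method is not stated. The authors also deposited 4 tables that set 1 library against 1 library. These give the ratio of normalized means, its log2 value, the unadjusted p-value and the adjusted p-value of the authors, for genes past an unadjusted p of 0.05 and a fold change of 2 only. The tool behind the deposited p-values is not stated. Infinite ratios stand in them where the control is 0. The deposited files hold 9 further columns of values per library that were not used here, 2 of which match no sample of the series.

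Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts, with TMM factors and a robust quasi-likelihood fit. The edgeR expression filter, at a minimum count of 10 and with the 4 groups given, kept 14726 genes. The common biological coefficient of variation was 0.440. A model with 1 mean per group gave 5 comparisons: knockout tumor against wild-type tumor, tumor against normal within each genotype, knockout normal against wild-type normal, and the difference between the 2 tumor effects. An additive model of genotype and tissue gave knockout against wild type over both tissues and tumor against normal over both genotypes. The knockout normal group is 1 library, which was assumed to vary like the other groups. P-values were adjusted with the Benjamini-Hochberg method over the genes of each comparison, at a threshold of 0.05. Values per library are CPM, the deposited counts scaled by the library total.

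Before the data were examined, 47 gene lists for metabolism, tumor state, sex and the cell types of liver were written down, of which 46 had at least 2 tested genes and sizes ran from 4 to 33. Each was set against all other tested genes with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. The same was done for 302 KEGG pathways of the deposited annotation that held 10 to 300 tested genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone.

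The rule for named genes, also fixed before the data were examined, took for the comparisons of knockout tumor with wild-type tumor, of tumor with normal, and of knockout with wild type: Nfib, the urea cycle list, up to 10 genes per direction past the threshold with a mean of at least 1 CPM and no overlap between libraries, and 4 members of each list past the camera threshold. With fewer than 3 genes past the threshold in a direction, it took the 5 with the smallest p. The other comparisons took 3 per direction. This rule named 99, 94 and 122 genes. The text prints members for the 6 lists with the smallest camera p, and for the urea cycle, a limit set after the number of called lists was seen. Fitted folds are left out for genes with almost no counts on 1 side of a comparison, and CPM values are given in their place. Gene positions are those of GRCm38 in the GENCODE annotation, in which 241 of 244 named genes had 1 locus.

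The tests were tried on simulated counts with 200 changed genes, after the first fit to the data. For knockout against wild type edgeR recovered 11.9% of genes changed 2-fold, 71.6% of those changed 4-fold and 87.9% of those changed 8-fold, and called 7 unchanged genes. For knockout tumor against wild-type tumor it recovered 1.49%, 43.3% and 65.2%, and called 2 unchanged genes. In the same simulations DESeq2 1.42.0 called 66 to 70 unchanged genes per comparison, and limma-voom called 2 to 5. The simulated counts were drawn independently for each gene and library, without foreign tissue, shared animals or a library that stands apart. The rates above may therefore not hold for the 8 libraries.

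The alternatives were DESeq2 size factors or library totals in place of TMM, no expression filter, a filter of 1 CPM in 2 libraries, limma-voom, the DESeq2 Wald test, FPKM plus 1 or plus 0.1 with a mean FPKM of at least 0.5 and FPKM plus 1 without that filter, 2 other thresholds, the replicate number as a block, the compared groups alone, no covariate, and each library left out in turn. Leaving out both wild-type libraries numbered 2, and leaving out both libraries with muscle transcripts, were alternatives chosen after seeing the data. The share of Alb in single libraries has a 95% Wilson interval, which covers counting error only, and CPM values of single libraries are given without one. The medians of called lists with each library left out, where they moved by over 1.5 times or the call ended, were tabulated for all comparisons after the results were seen.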

Results

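The series measured liver RNA in mice with a hepatocyte deletion of Nfib, which encodes a transcription factor of the nuclear factor I family, and its title concerns hepatocellular tumors and the urea cycle. The 8 libraries comprised 3 wild-type tumors, 2 wild-type normal livers, 2 knockout tumors and 1 knockout normal liver. Total counts were 17603602, 19965842 and 15721988 in wild-type tumors 1, 2 and 3, and 11912549 and 17453336 in wild-type normal livers 2 and 3. They were 17435886 and 17180573 in knockout tumors 2 and 3, and 16909658 in knockout normal liver 3. Alb, which encodes serum albumin, took 5.05% of the counts in wild-type normal 2 (95% interval 5.04% to 5.06%) and 14.09% in wild-type tumor 2 (14.07% to 14.10%).

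Nfib transcripts were not lower in the libraries labelled knockout. Nfib, at 82290173 to 82705750 on chromosome 4 of GRCm38, gave 82.8 ± 4.87 CPM (SD, n = 3) in the knockout libraries and 73.2 ± 23.3 CPM (SD, n = 5) in the wild-type libraries. The counts were 1534, 1346 and 1386 in knockout tumor 2, knockout tumor 3 and knockout normal 3, against 828 to 1356 in the 5 wild-type libraries. The log2 fold change of knockout over wild type, with tissue in the model, was 0.27 ± 0.19 (SE), or 0.14 without wild-type tumor 2, and edgeR gave it an adjusted p of 0.748 over all libraries. A count over the whole gene does not resolve a deleted exon, for which 12 transcripts are annotated at this locus, and cells other than hepatocytes keep the gene. These counts also leave open a mix-up of labels or libraries, which was not tested and would change what each knockout comparison means. The genotype names below are therefore those of the labels.

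Several libraries stood apart in groups of genes named below. Wild-type tumor 2 held the oncofetal transcripts Afp at 2112 CPM and Igf2 at 5185 CPM, and wild-type tumor 1 held Afp at 543 CPM, while wild-type tumor 3 had Afp at 4.64 CPM. Wild-type tumor 3 correlated with wild-type normal 3 at Pearson r = 0.984 across tested genes, which are not independent replicates. Skeletal muscle transcripts were abundant in knockout tumor 2, with Acta1 at 880 CPM, and in knockout normal 3, with Acta1 at 223 CPM, and were seen at a lower level in wild-type tumor 1, with Acta1 at 29.7 CPM. The other 5 libraries had Acta1 at 4.58 CPM or less. The squamous keratin Krt13 reached 213 CPM in knockout tumor 2 and at most 0.284 CPM elsewhere. The neutrophil gene S100a8 stood at 64.3 CPM in knockout tumor 3 and 64.2 CPM in knockout normal 3, and at 4.59 to 12.3 CPM in the other 6 libraries. Y-linked Ddx3y gave 59.9 CPM in wild-type normal 2 and 5.31 CPM in wild-type tumor 2, and at most 0.118 CPM elsewhere.

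**Figure D1:**
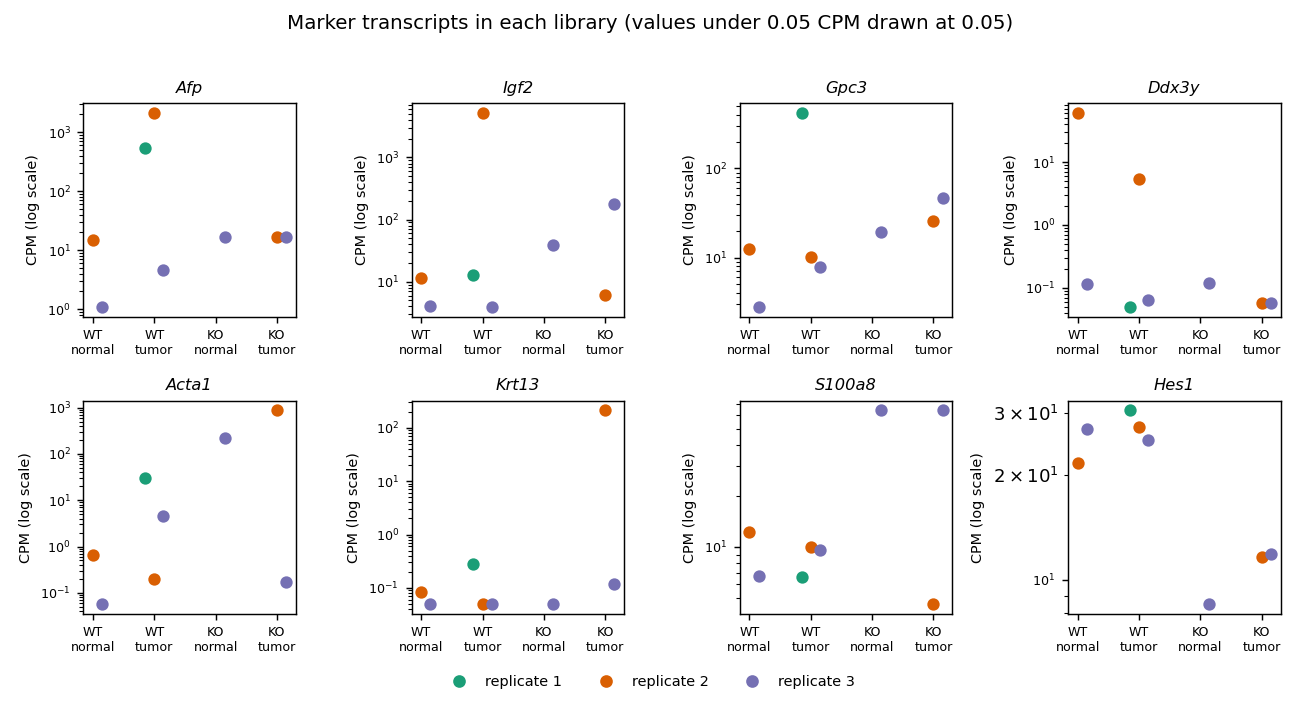
CPM on a log axis (y) of 8 marker genes in the 4 groups (x), with 1 point per library colored by replicate number. Acta1 and Krt13 are high in knockout tumor 2, Afp in wild-type tumors 1 and 2, and Hes1 lies between 8.52 and 11.9 CPM in the 3 knockout libraries and between 21.6 and 30.6 CPM in the 5 wild-type libraries.

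The comparison of knockout with wild-type tumors addresses the question in the title. No gene passed in edgeR, and camera called the lists below at the preset correlation but none with an estimated correlation. Enzymes of amino acid breakdown were higher in the knockout tumors (32 of 33 genes, median log2 fold change 0.71), among them Cth, which makes cysteine, at 0.98 ± 0.39 (SE, n = 2 and 3), Mccc1 at 0.61 ± 0.19 and Agxt2 at 0.57 ± 0.25 (0.37 without wild-type tumor 2). The urea cycle list was also higher, with 8 of 9 genes up and a median of 1.08, and without wild-type tumor 2 the median was 0.58. Oncofetal and tumor markers were lower in 21 of 22 genes (median -1.66), including Afp at -5.88 ± 2.43, Golm1 at -2.26 ± 0.90, Anxa2 at -1.95 ± 0.81 and Cd44 at -0.72 ± 0.20, and the median was -0.86 without wild-type tumor 1 and -0.83 without wild-type tumor 2. All 25 genes of the G2 and mitosis list were lower (median -0.88), with Ccnb2 at -1.68 ± 0.75 and Bub1 at -2.13 ± 1.06, which was at -3.45 without knockout tumor 3 and -1.46 without knockout tumor 2. Genes of the unfolded protein and integrated stress response were lower in 20 of 21 (median -0.64), with Trib3 at -2.99 ± 1.21, Ddit3 at -2.97 ± 1.39 and Atf5 at -0.98 ± 0.46. Wild-type tumor 3 ran the other way in these 3 lists, with a mean deviation below those of knockout tumors 2 and 3 (-0.55 against -0.35 and 0.13 for mitosis, -0.87 against -0.57 and 0.22 for oncofetal markers, and -0.37 against -0.33 and -0.14 for stress). For the stress list its median deviation lay above that of knockout tumor 2 (-0.28 against -0.34). Without wild-type tumor 2 the stress list had a median of -0.39, Trib3 was at -1.45 and Ddit3 at -0.39.

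Interferon genes were higher in 16 of 18 (median 0.57), with Rsad2 at 1.54 ± 0.51, Gbp3 at 1.53 ± 0.49 and Gbp2 at 0.84 ± 0.26, and the median of that list was -0.09 and not called without knockout tumor 3, 1.10 without knockout tumor 2 and 0.90 without wild-type tumor 3. Without knockout tumor 3 Rsad2 was at 0.57, Gbp3 at 0.81 and Gbp2 at 0.53. Camera at the preset correlation gave adjusted p of 4.69e-13 for amino acid breakdown, 4.87e-07 for the oncofetal list, 3.47e-06 for the stress list, 5.07e-06 for mitosis, and 8.15e-06 for both interferon genes and the urea cycle. All 6 lists had an adjusted p = 0.614 with an estimated correlation. Camera called 22 of 46 lists, 13 higher and 9 lower, and none with an estimated correlation or by fry. Of the 302 KEGG pathways it called 31, 24 of them higher, and 0 with an estimated correlation, where the smallest adjusted p was 0.832. Among these, arginine biosynthesis had a median of 0.68 over 19 genes with an adjusted p of 1.23e-04, and protein processing in endoplasmic reticulum a median of -0.26 over 152 genes with an adjusted p of 1.23e-04, both with adjusted p = 0.832 with an estimated correlation.

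No single gene passed in this comparison. In edgeR 0 of 14726 genes had an adjusted p under 0.05, the smallest being 0.888, while 430 had an unadjusted p under 0.05, against 736 expected by chance. No member of these lists passed in edgeR over all genes or adjusted over the list alone. Limma-voom called 0 genes and DESeq2 called 4 (Krt15, Lyg2, Sertm1 and Tgm3), named after their values were seen. The genes with the smallest p were, on the higher side, Acpp at 1.53 ± 0.31 and 2410131K14Rik at 1.11 ± 0.24, together with Dapl1, Krt4 and Tgm3, which had almost no counts in the wild-type tumors. On the lower side they were Hes1, a Notch target, at -1.29 ± 0.25, Ugt2b37 at -1.64 ± 0.40, Muc4 at -4.55 ± 1.13, Fam73a at -2.02 ± 0.52 and Phc1 at -1.30 ± 0.34. Krt4 stood at 172 CPM in knockout tumor 2 and 0.291 CPM in knockout tumor 3, and Tgm3 at 28.6 and 0.0582 CPM. The count at an unadjusted p under 0.05 was 1631 without wild-type tumor 3, 221 without knockout tumor 2, and 243 to 286 without each of wild-type tumors 1 and 2 and wild-type normals 2 and 3, with 0 genes called each time.

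Over both tissues, most urea cycle genes had a higher fitted level in the 3 libraries labelled knockout than in the 5 wild-type libraries. None passed in edgeR over all genes, and camera called the list at the preset correlation but not with an estimated correlation. Cps1, which carries out the first step of the cycle, stood at 5086 ± 1054 CPM (SD, n = 3) against 2387 ± 795 CPM (SD, n = 5), a log2 fold change of 1.20 ± 0.26 (SE). Ass1 gave 1.23 ± 0.55, Asl 1.27 ± 0.48, Slc25a15, the mitochondrial ornithine carrier, 1.21 ± 0.39 and Arg1 0.87 ± 0.58. Otc gave 0.44 ± 0.35, Slc25a13 0.48 ± 0.34 and Nags 0.34 ± 0.15, and of the 9 genes only Arg2 was lower, at -0.87 ± 0.63. Without wild-type tumor 2 Arg1 was at 0.53, Otc at 0.23 and Slc25a13 at 0.28, without wild-type tumor 3 Otc was at 0.74, and without knockout tumor 3 Arg2 was at -1.37. Every knockout library lay above every wild-type library for 3 of the 9 genes (Cps1, Ass1 and Slc25a15). Chance gives this for 1.79% of genes if the 8 libraries are independent, which the labels do not settle for equal replicate numbers, and 3.47% of all tested genes showed it.

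**Figure D2:**
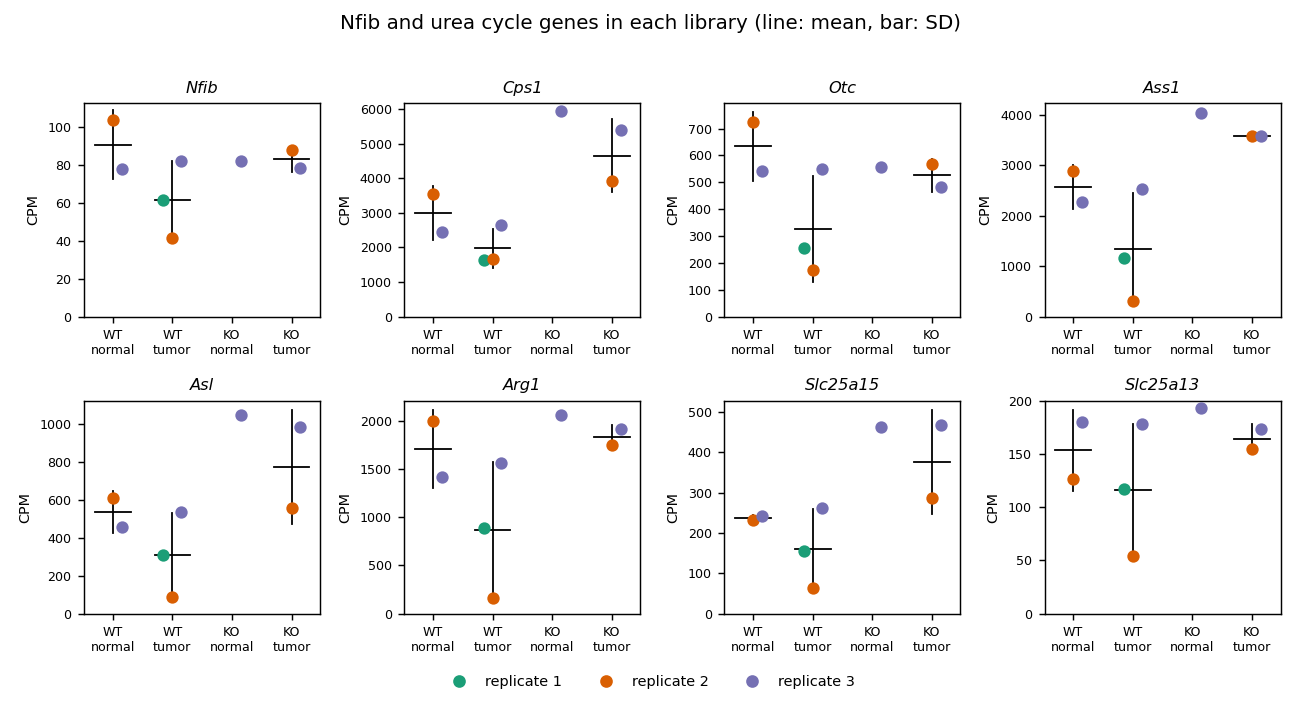
CPM (y) of Nfib and 7 urea cycle genes in the 4 groups (x), with 1 point per library colored by replicate number. Horizontal lines are means and vertical bars SD, and the knockout normal group is 1 library. Cps1 runs from 3909 to 5942 CPM in the knockout libraries and from 1642 to 3556 CPM in the wild-type libraries.

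The urea cycle list had a median of 0.87 over its 9 genes, 8 of them higher, and camera gave it an adjusted p of 2.92e-06, with adjusted p = 0.408 with an estimated correlation. In edgeR Cps1 passed adjusted over the list alone and 0 members passed over all genes, while DESeq2 called Cps1 over all genes with an adjusted p of 1.66e-04. Without wild-type tumor 2, whose mean over the list was the lowest of the 8 libraries, the median was 0.53, and without knockout tumor 3 it was 0.71. In the test of knockout normal against wild-type normal the list had a median of 0.47 with 7 of 9 genes higher and an adjusted p of 0.0115, with adjusted p = 0.618 with an estimated correlation. That call was lost without wild-type normal 2 (median 0.56, camera adjusted p 0.0711), and the median was 0.80 without wild-type normal 3. The difference between the 2 tumor effects was not called for this list, with a median of 0.19 and an adjusted p of 0.258.

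Other metabolic lists were higher over both tissues as well. Amino acid breakdown was higher in 32 of 33 genes (median 0.58, camera adjusted p 9.28e-14), with Mat1a, which makes S-adenosylmethionine, at 1.33 ± 0.45, Ahcy at 0.81 ± 0.24, Mccc1 at 0.59 ± 0.14 and Agxt2 at 0.53 ± 0.18. Gluconeogenesis and glycogen genes were higher in 13 of 14 (median 0.52, adjusted p 2.42e-05), with Ppp1r3g at 1.84 ± 0.68, Slc37a4 at 0.90 ± 0.41, Pygl at 0.61 ± 0.22 and Gbe1 at 0.59 ± 0.22. Both had an adjusted p = 0.408 with an estimated correlation, and no member passed in edgeR adjusted over the list alone. Without wild-type tumor 2 the gluconeogenesis and glycogen median was 0.33. The plasma proteins made by hepatocytes had a median of 0.03 over 23 genes.

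Neutrophil genes were higher in 12 of 13 (median 2.35), with Elane at 3.31 ± 0.81, Mmp8 at 2.85 ± 0.92, S100a8 at 2.35 ± 0.70 and S100a9 at 2.31 ± 0.63. Interferon genes were higher in 17 of 18 (median 0.77), with Gbp3 at 1.71 ± 0.37, Ifit1 at 1.32 ± 0.36, Ifi44 at 1.26 ± 0.40 and Gbp2 at 0.91 ± 0.19. Neutrophil genes were high in knockout tumor 3 and knockout normal 3 and were lowest of the 8 libraries in knockout tumor 2. The libraries with high values share the number 3, and the labels do not settle whether they come from 1 animal. Camera gave adjusted p of 7.92e-10 for neutrophil genes and 9.38e-10 for interferon genes, each with adjusted p = 0.408 with an estimated correlation. Without knockout tumor 3 the neutrophil median was 1.46, with Elane at 1.96, Mmp8 at 1.72, S100a8 at 1.43 and S100a9 at 1.44, and the interferon median was 0.42. Ifi44 was at 0.80 without knockout normal 3, a fit that compares knockout tumor with wild-type tumor only. In edgeR 9 neutrophil genes and 3 interferon genes passed adjusted over the list alone and 0 over all genes, while DESeq2 called Elane, Gbp2 and Gbp3 over all genes with adjusted p of 0.0462, 0.0495 and 0.0287. Muscle genes were higher in 12 of 12 (median 3.59, adjusted p 1.37e-05, and adjusted p = 0.442 with an estimated correlation), with Acta1 at 6.62 ± 2.26, Ckm at 5.90 ± 1.95, Mylpf at 4.66 ± 1.21 and Actn3 at 4.05 ± 1.37. In edgeR no muscle gene passed, and DESeq2 called Mylpf with an adjusted p of 0.00593. The call of the list was lost without knockout tumor 2 (median 3.95, camera adjusted p 0.476). Without the 2 libraries richest in muscle transcripts, an alternative chosen after seeing the data, the muscle list had a median of -3.30, with wild-type tumor 1, which also held muscle transcripts, still on the wild-type side. That fit set knockout tumor 3 alone against the wild-type tumors.

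Camera called 28 of the 46 lists over both tissues, 16 higher and 12 lower, and 42 of the 302 KEGG pathways, 31 of them higher, and none of either with an estimated correlation. The arginine biosynthesis pathway had a median of 0.79 over 19 genes and an adjusted p of 8.18e-06, and the citrate cycle a median of 0.32 over 30 genes and an adjusted p of 1.64e-05, both with adjusted p = 0.771 with an estimated correlation. The number of KEGG pathways called was 21 without knockout tumor 2 and 27 without wild-type tumor 2.

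**Figure D3:**
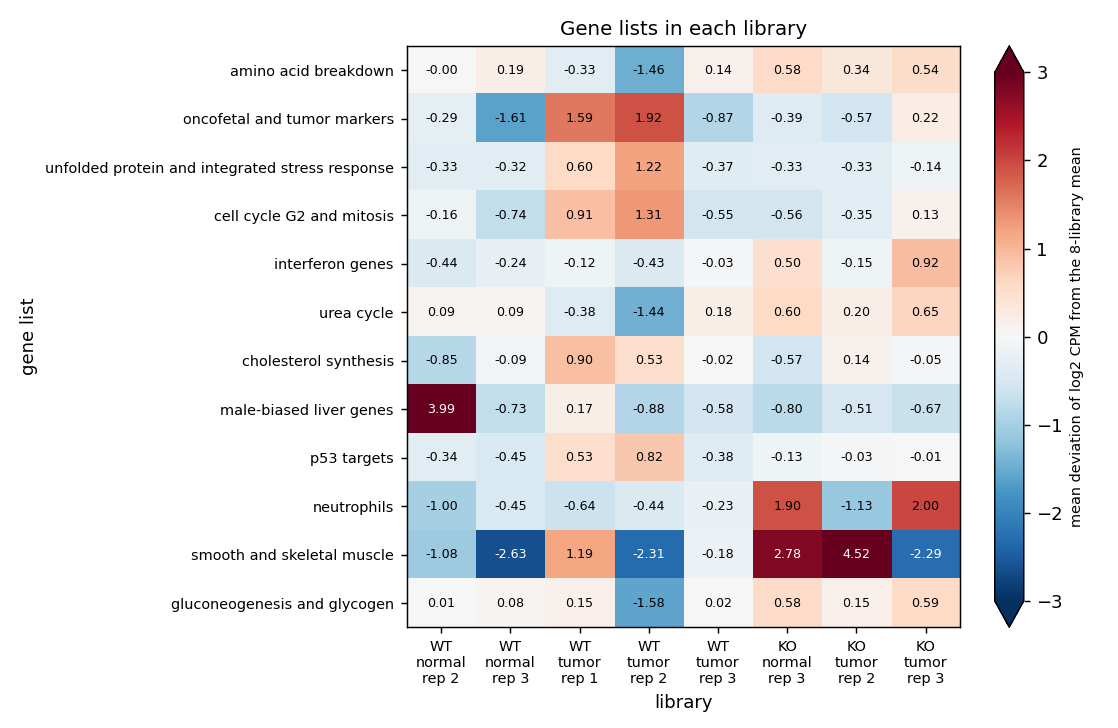
Mean deviation of log2 CPM from the mean of the 8 libraries for 12 gene lists (y) in each library (x), printed in each cell and colored from blue (lower) to red (higher). Wild-type tumor 2 has the lowest urea cycle value at -1.44 and the neutrophil list its lowest value in knockout tumor 2 at -1.13.

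No single gene passed over both tissues. EdgeR called 0 of 14726 genes, with a smallest adjusted p of 0.705, while 1009 genes had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 45. The unadjusted count was 371 without knockout normal 3 and 529 without knockout tumor 3, against 736 expected by chance in the fit of all libraries. Without knockout normal 3 no knockout normal liver is left, and that fit compares knockout tumor with wild-type tumor only. It was 1195 without wild-type tumor 2 and 1399 without wild-type tumor 3. Hes1, at 30064384 to 30067796 on chromosome 16, was at 10.7 ± 1.86 CPM (SD, n = 3) in knockout and 26.3 ± 3.30 CPM (SD, n = 5) in wild-type libraries, a log2 fold change of -1.32 ± 0.18 (SE) with an edgeR adjusted p of 0.705. The other genes of smallest p on the lower side were Ugt2b37 at -1.56 ± 0.29, Tuba1b at -0.68 ± 0.13, Rbpms at -0.74 ± 0.15 and Muc4 at -4.64 ± 0.96. On the higher side they were 2410131K14Rik at 1.07 ± 0.17, Acpp at 1.34 ± 0.24, Gsta4, a glutathione transferase, at 0.68 ± 0.13, Chil1 at 2.53 ± 0.50 and Slc2a4, the insulin-regulated glucose transporter, at 3.01 ± 0.62. Without knockout tumor 2 edgeR called S100a8 at 2.92 and S100a9 at 2.85. The knockout side was then knockout tumor 3 and knockout normal 3 only. Both carry the number 3, and if they come from 1 animal, which the labels do not settle, they are not independent replicates.

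In tumor against normal no gene passed in edgeR, and camera called the lists below at the preset correlation but none with an estimated correlation. Tumor libraries of both genotypes had higher cholesterol synthesis transcripts than normal liver, with genotype in the model. All 22 genes of that list were higher (median 0.85), with Sqle, which oxidizes squalene, at 1.44 ± 0.41 (SE, n = 5 and 3), Mvd at 1.18 ± 0.33, Fdps at 1.11 ± 0.29 and Dhcr7 at 0.99 ± 0.31. All 25 G2 and mitosis genes were higher (median 0.93), with Cdc20 at 1.71 ± 0.62, Tpx2 at 1.68 ± 0.61, Prc1 at 1.59 ± 0.62 and Ccna2 at 1.08 ± 0.38. Oncofetal and tumor markers were higher in 21 of 22 (median 1.51), with Ly6d at 2.96 ± 0.98, Scd2 at 2.28 ± 1.16, Prom1 at 1.49 ± 0.62 and Anxa5 at 0.68 ± 0.35, and p53 targets in 18 of 19 (median 0.49), with Phlda3 at 1.71 ± 0.71 and Btg2 at 1.10 ± 0.41. The oncofetal median was 0.91 without wild-type tumor 2, where Anxa5 was at 0.43, and 0.97 without wild-type normal 3, where the mitosis median was 0.61. Not every tumor exceeded every normal liver, since wild-type tumor 3 and knockout tumor 2 had mean deviations below wild-type normal 2 for mitosis (-0.55 and -0.35 against -0.16) and for oncofetal markers (-0.87 and -0.57 against -0.29), as had wild-type tumor 3 for p53 targets (-0.38 against -0.34).

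Amino acid breakdown genes were lower in tumor in 29 of 33 (median -0.33), with Hal at -0.74 ± 0.55, Tdo2 at -0.61 ± 0.47 and Kynu at -0.42 ± 0.24, and the urea cycle in 8 of 9 (median -0.43). The amino acid median was -0.14 without wild-type tumor 2, where Hal was at -0.39 and Tdo2 at -0.35, -0.20 without wild-type normal 3 and -0.50 without wild-type tumor 3, where Hal was at -1.17 and the urea cycle median was -0.70. Hal was at -1.13 without knockout normal 3, a fit that compares tumor with normal within wild type only. Kynu was at -0.23 without wild-type normal 2. Male-biased liver genes were lower in 18 of 20 (median -2.05), with Mup1 at -5.96 ± 1.85, and this rested on wild-type normal 2, the library rich in Y-linked reads. Without that library the male-biased median was 0.37 and not called, and Mup1 was at -1.74. Camera adjusted p were 6.18e-24 for cholesterol synthesis, 4.02e-12 for mitosis, 4.18e-08 for oncofetal markers, 8.88e-08 for male-biased genes, 2.88e-06 for p53 targets, 5.58e-06 for amino acid breakdown and 0.00235 for the urea cycle. Each of these 7 had an adjusted p = 0.718 with an estimated correlation. Camera called 21 lists, 10 higher and 11 lower, and 10 KEGG pathways, led by steroid biosynthesis with a median of 0.70 over 16 genes and an adjusted p of 5.36e-08, and none with an estimated correlation, the smallest pathway value being 0.984. The number of pathways was 3 without wild-type normal 3, 5 without wild-type tumor 1 or knockout tumor 3, 6 without wild-type tumor 2, 17 without wild-type tumor 3 and 33 without wild-type normal 2.

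EdgeR called 0 of 14726 genes in the comparison of tumor with normal, with a smallest adjusted p of 0.922. An unadjusted p under 0.05 was found for 259 genes, limma-voom called 0 and DESeq2 called 5 (Lgals7, Lyg2, Serpinb3c, Sim2 and Sprr3), named after their values were seen. None of the list members passed in edgeR over all genes or adjusted over the list alone. The genes of smallest p were Scd3, a stearoyl desaturase, at 3.03 ± 0.72, Ceacam2 at 2.56 ± 0.62, Sec14l5, Aqp7 and the agouti gene a on the higher side. Sec14l5, Aqp7 and a had almost no counts in normal liver. On the lower side they were Sox12 at -0.83 ± 0.20, Sla2 at -1.22 ± 0.41, Ndufb4 at -0.43 ± 0.15, Mup1, and Hsd3b5, which was at 220 CPM in wild-type normal 2 and at most 0.852 CPM elsewhere. The count at an unadjusted p under 0.05 was 986 without wild-type tumor 3, 130 without wild-type tumor 1, 137 without wild-type normal 3 and 164 without wild-type normal 2.

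Within wild type, camera called 21 lists in tumor against normal. Cholesterol synthesis was higher in 22 of 22 genes (median 0.96, camera adjusted p 4.06e-15), mitosis in 25 of 25 (median 1.14, 3.34e-10), oncofetal markers in 20 of 22 (median 2.25, 3.34e-10), and sinusoidal endothelial genes were lower in 18 of 18 (median -0.60, 8.52e-06), all with adjusted p = 0.664 with an estimated correlation. The endothelial median was -0.17 without wild-type tumor 2 and -1.28 without wild-type tumor 3, whose mean deviation over that list, 0.66, was the highest of the 5 wild-type libraries. The cholesterol median was 0.48 without wild-type normal 2 and 1.45 without wild-type normal 3, and the oncofetal median 1.43 without wild-type tumor 2. Wild-type tumor 3 had mean deviations below wild-type normal 2 for mitosis (-0.55 against -0.16) and oncofetal markers (-0.87 against -0.29). Scd3 was at 3.75 ± 0.94 (SE, n = 3 and 2), Tuba8 at 1.52 ± 0.38 and Stambpl1 at 1.43 ± 0.37, and Mup1, Mup7 and Abcb10 led the lower side, Abcb10 at -0.70 ± 0.18. The direction of Mup7 rested on wild-type normal 2, the library rich in Y-linked reads, and without it Mup7 was at 1.46. EdgeR called 0 genes, with a smallest adjusted p of 0.845 and 341 genes at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 15. The unadjusted count was 2175 without wild-type tumor 3, 117 without wild-type normal 2, 129 and 127 without wild-type tumors 1 and 2, and 189 and 184 without knockout tumors 2 and 3.

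Within knockout, where normal liver is 1 library, cholesterol synthesis was higher in the tumors in 22 of 22 genes (median 0.62, camera adjusted p 6.08e-11, and adjusted p = 0.958 with an estimated correlation). Camera also called stellate cell and matrix genes higher in 22 of 22 (median 0.90, 1.17e-05), and neutrophil genes lower in 12 of 13 (median -0.70, 8.80e-09) and acute phase genes in 18 of 21 (median -0.58, 2.29e-07), each with adjusted p = 0.958 with an estimated correlation. These 3 calls rested on knockout tumor 2, and without it the medians were -0.03, 0.06 and -0.18 and none was called. Without knockout tumor 3 the neutrophil median was -3.41 and the acute phase median -1.15. Among genes of smallest p, Trim2 was at 1.02 ± 0.33 (SE, n = 2 and 1), A430105I19Rik at 1.10 ± 0.35 and Ing3 at -0.80 ± 0.27, Sec14l5 was counted only in the tumors, and Acp7 and Tmem52 were at 0 counts in both tumors, with 58 and 24 counts in the normal liver. EdgeR called 0 genes, with a smallest adjusted p of 1 and 30 genes at an unadjusted p under 0.05, limma-voom and DESeq2 called 0, and camera called 10 lists, or 5 without knockout tumor 2. The unadjusted count ran from 15 without wild-type tumor 1 to 229 without knockout tumor 3.

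In the test of knockout normal liver, again 1 library, against wild-type normal liver, camera called inflammatory lists. Neutrophil genes were higher in 12 of 13 (median 2.96, camera adjusted p 3.83e-16), acute phase genes in 20 of 21 (median 0.94, 1.29e-09) and interferon genes in 15 of 18 (median 0.74, 1.89e-09), all with adjusted p = 0.498 with an estimated correlation. With 1 library the test does not separate the group from that sample, and knockout tumor 3 had similar mean deviations for neutrophil genes (1.997 against 1.900) and acute phase genes (0.78 against 0.94). Slc22a12 was at 4.02 ± 0.89 (SE, n = 1 and 2), Cyp2g1 at 3.13 ± 0.82, Trim2 at -1.41 ± 0.33, Hes1 at -1.37 ± 0.34 and Peg10 at -3.64 ± 0.99, and Acp7 had 0 counts in both wild-type normal livers. EdgeR called 0 genes, with a smallest adjusted p of 1 and 207 genes at an unadjusted p under 0.05, limma-voom called 0, DESeq2 called 1 (Eif2s3y, which is Y-linked), and camera called 21 lists. The unadjusted count ran from 80 without wild-type normal 2 to 465 without wild-type tumor 2. Fitted on these groups alone, edgeR called 7 genes (Ckm, Mb, Myh1, Mylpf, Ren1, Tcap and Tnnt3), named after their values were seen and holding muscle genes.

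The test of whether the tumor effect differed by genotype called 0 genes in edgeR, limma-voom and DESeq2, with a smallest edgeR adjusted p of 0.9999 and 47 genes at an unadjusted p under 0.05, which ran from 15 without wild-type tumor 1 to 530 without wild-type tumor 3. Plvap, an endothelial gene, was at 1.29 ± 0.44 (SE, n = 8), A430105I19Rik at 1.25 ± 0.42, Exoc4 at -1.25 ± 0.43 and Tnnc1 at -3.24 ± 1.15, beside Fam217a and Acp7, which had almost no counts in 1 group. Camera called 20 lists, 7 higher and 13 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.701. Sinusoidal endothelial genes were higher in 18 of 18 (median 1.03, adjusted p 6.34e-07, and adjusted p = 0.701 with an estimated correlation), with a median of 0.49 without wild-type tumor 2 and 1.64 without wild-type tumor 3.

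The authors deposited comparisons of single libraries, without replicates. Knockout tumor 3 over knockout normal 3 listed 317 genes (101 higher), wild-type tumor 2 over wild-type normal 2 listed 1001 (411 higher) and wild-type tumor 3 over wild-type normal 3 listed 270 (257 higher). Genes called in the knockout pair numbered 3 went the same way in 67.5% of cases in the wild-type pair numbered 2, where all tested genes did so in 57.3%, and in 36.3% in the wild-type pair numbered 3, where all tested genes did so in 51.1%. Calls of wild-type pair 2 went the same way in 49.95% in wild-type pair 3, where all tested genes did so in 45.1%, and in 68.6% in the knockout pair, against 57.3%. Calls of wild-type pair 3 did so in 34.4% in wild-type pair 2, against 45.1% of all tested genes, and in 39.6% in the knockout pair, against 51.1%. These percentages compare signs of genes, which are not independent replicates, and they are not tested. The remaining table is named for wild-type tumor 1 against knockout tumor 2, but its header names a control outside the 8 libraries. It lists 785 genes, 658 of them higher, and its finite log2 fold changes of genes matched to the FPKM values correlated at Pearson r = 0.368 with those computed against knockout tumor 2 and at 0.775 with those against wild-type normal 3, while the other 3 tables gave 0.891 to 0.985 with their named controls. It was not used here as a comparison of genotypes.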

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

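The tests of a knockout effect on muscle genes, of a male animal, of the 3 urea cycle explanations and of all splits of the libraries were chosen after the result was seen. The 2 further marker lists for muscle and squamous epithelium were written before their own values were looked at, but after related genes had been seen. Myh4, Pvalb and Mb of the second muscle list are an exception, as they also belong to the fixed muscle list behind the pattern. The wording of these 2 explanations was shortened afterwards.

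Muscle and squamous transcripts in libraries labelled knockout were a first pattern, with Acta1 at 880 CPM in knockout tumor 2 and 223 CPM in knockout normal 3, and with the interaction of the muscle list, tested by camera, at a median of -4.19. A knockout effect on muscle genes in every knockout library is argued against by knockout tumor 3, where 0% of the 12 genes of the fixed muscle list lay above every wild-type library, also with wild-type tumor 1, which held muscle transcripts, set aside, while an effect in single animals stays open. A second list of 25 muscle genes was used to test for skeletal muscle tissue. The share at 10 or more times the median of the other 6 libraries was 88% in knockout tumor 2. Such tissue may explain the signal there. In knockout normal 3 the share was 80%, exactly at the bound set beforehand for both libraries. Myh4, Pvalb and Mb of this list are also in the fixed muscle list, so they restate the pattern. Each counts toward the share, which without them falls below the bound in knockout normal 3, so the test cannot decide there. For squamous epithelium in knockout tumor 2 the second list gave 66.7% (14 of 21 detected genes), short of the 80% set beforehand, so this stays open. No sort that would remove such tissue is described in the labels.

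Y-linked reads in both wild-type libraries numbered 2 were a second pattern. A male animal behind wild-type normal 2 fits the male-biased liver genes, of which 95% (19 of 20) were highest in that library. Their mean deviation there, 3.99, lay far from the other 4 wild-type libraries, and the interaction of that list had a median of 3.19. RNA of wild-type normal 2 in wild-type tumor 2 would carry over every gene high in the normal library. Their ratios would then lie near or above the Y-linked ratios of 0.0486 to 0.0886. The 36 such genes had a median ratio of 0.0149 in the tumor, with quartiles of 0.00347 and 0.0802. That median, below the lowest Y-linked ratio, argues against this source of the Y-linked reads, for these genes. The rule set beforehand left it open, as the upper quartile reaches the Y-linked ratios. Sex of the animals is not given in the labels and stays open. Y-linked Ddx3y was at trace level in every knockout library, so the Y-linked reads lie on the wild-type side of each genotype comparison. Sex was in no model, and a difference in sex between the genotype groups is not separated from genotype.

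Higher urea cycle genes in libraries labelled knockout were another pattern, with a call by camera that is lost with an estimated correlation (adjusted p = 0.408). Leaving out wild-type tumor 2 lowered the list median from 0.87 to 0.53. That library thus accounts for a part of the size but not for the direction. Camera at the preset correlation still called the list, with an adjusted p of 1.60e-06 (1.99e-07 to 0.00180 for list urea cycle over all libraries left out in turn). With an estimated correlation camera gave an adjusted p of 0.524. The preset call says little here, as 28 of 46 lists had it. Without knockout tumor 2 and knockout normal 3 the median was 1.19, from knockout tumor 3 alone against the wild-type tumors. In knockout tumor against wild-type tumor with all libraries it was 1.08. The higher level was thus not confined to those libraries. This cannot decide on tissue other than liver in them, since tissue poor in urea cycle transcripts would lower the list rather than raise it. A larger share of hepatocyte RNA that raised all its transcripts alike is argued against by the plasma protein list. That list had a median of 0.0317 and an upper quartile of 0.16, against a median of 0.87 for the urea cycle. It cannot exclude other differences in hepatocyte content. Alb had its highest share, 14.09%, in wild-type tumor 2, the library lowest for the urea cycle, and other metabolic lists were higher as well. Hepatocyte content, genotype and differences between single animals stay open.

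Libraries far from the others were looked for in total counts, Nfib, the gene lists shown per library and the single urea cycle genes. Each was taken among the wild-type libraries and among the tumors, and other lists were not looked at. Of these 46 sets of 5 libraries, 4 held a library far from the others, where chance alone gives about 1 in 20. Besides the male-biased list, the neutrophil list stood at 1.997 in knockout tumor 3 among the tumors, and gluconeogenesis and glycogen stood at -1.58 in wild-type tumor 2, both among the wild-type libraries and among the tumors.

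Camera called a tumor effect that differed between genotypes for further lists, none with an estimated correlation. The medians of the difference were -1.61 for oncofetal and tumor markers, -0.51 for G2 and mitosis, -0.82 for p53 targets, -0.53 for the unfolded protein and integrated stress response and -0.90 for neutrophil genes. They were 0.27 for amino acid breakdown and -0.19 for cholesterol synthesis. The call was lost for mitosis without wild-type tumor 2 (-0.23), wild-type normal 3 (-0.28) or knockout tumor 2 (-0.36), and for neutrophil genes without knockout tumor 2 (-0.08). It was lost for amino acid breakdown without wild-type tumor 1, wild-type tumor 2, wild-type normal 3 or knockout tumor 3 (0.28, -0.01, 0.15 and 0.10), and for cholesterol synthesis without wild-type tumor 1, wild-type normal 2 or knockout tumor 3 (-0.05, 0.16 and -0.15). The muscle list lost it without wild-type normal 3 (-3.71) or knockout tumor 3 (-3.24), and the male-biased list without wild-type normal 2 (-0.31). The oncofetal median was -0.95 without wild-type tumor 1 and -2.50 without wild-type normal 2.

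Other splits of the 8 libraries were tested for both additive comparisons. For knockout against wild type edgeR called 0 genes, so all 55 splits of 55 gave as many by construction, which says nothing about chance, the highest other split giving 33. For tumor against normal the real count was also 0 and 55 of 55 splits gave as many, with nothing learned about chance, the highest other giving 921. At an unadjusted p under 0.05, 13 of 55 splits gave at least the 1009 genes of the real genotype split, the highest other giving 3173, and 35 of 55 gave at least the 259 genes of the real tissue split, the highest other giving 4389. Chance is not excluded for either unadjusted count. The split with 921 genes set wild-type tumor 3 beside the 2 wild-type normal livers, which points to a structure of the samples in which that tumor library groups with normal liver.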

How the results depend on the processing

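Leaving out both wild-type libraries numbered 2, and both libraries with muscle transcripts, were tests chosen after the result was seen, and the other alternatives were planned. Of 3486 values of single genes over the alternatives, 3358 kept their direction and stayed uncalled, 105 were called and 23 reversed. No gene passed in the main fits, so none could lose a call. Of the 105, 82 came from the main fit read at an unadjusted p with a fold of at least 2, a looser threshold. The rest were 18 with DESeq2, 3 with FPKM plus 1 without filter and 2 without knockout tumor 2. The cause was not tested for any change below unless it is named.

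For 0 genes called by edgeR in each of the 7 comparisons, DESeq2 gave 4 genes in knockout tumor against wild-type tumor, 15 within wild type, 1 in knockout normal against wild-type normal, 5 in tumor against normal and 45 in knockout against wild type, and limma-voom gave 0. DESeq2 also called 66 to 70 unchanged genes in simulated counts. Those were drawn independently for each gene and library, so that number may not hold for these data. An unadjusted p under 0.05 with a fold change of at least 2 gave 257, 243, 26, 140, 41, 155 and 414 genes for knockout against wild-type tumor, tumor against normal in wild type and in knockout, knockout against wild-type normal, the difference of tumor effects, tumor against normal, and knockout against wild type. FPKM plus 1 without filter called 1 gene (Acp7) in each of the 3 comparisons that use knockout normal alone. Fitted on the compared groups alone, knockout normal against wild-type normal gave 7 genes. With 1 library left out, knockout against wild type gave 0 to 2 genes, the 2 being S100a8 and S100a9 without knockout tumor 2, and the other 6 comparisons gave 0. That fit leaves knockout tumor 3 and knockout normal 3, which share a number and may come from 1 animal. With the replicate number as a block, within genotypes, across them or as a random effect, 0 genes were called in all 7, and Nfib in knockout against wild type was at 0.26 with the block across genotypes. As a random effect the replicate number lowered the unadjusted count of knockout against wild type from 751 in limma-voom to 521, at a correlation of 0.237. The labels give only a shared number. Deviations from group means correlated at 0.16 and 0.20 in the 2 wild-type pairs, and the knockout pair has no such value, its normal group being 1 library. The wild-type normal group holds 2 libraries, whose deviations mirror each other, so the values of the wild-type pairs are not independent of each other. Deviations from tissue means, which keep genotype differences, correlated at 0.193, 0.327 and 0.204 in wild-type pairs 2 and 3 and knockout pair 3, each library of a pair correlating best, across tissues, with its own number, a hint from the data (knockout tumor 2 gave 0.203 with knockout normal 3). Residuals of the additive model gave -0.0732, 0.399 and -0.156.

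With an estimated correlation and with fry, 0 lists were called in the 7 comparisons and 0 KEGG pathways in the 3 where pathways were tested, and the urea cycle list, at medians of 1.08, -0.43 and 0.87, was no longer called. With 1 library left out the lists called within knockout ran from 5 to 13, the 5 without knockout tumor 2, and KEGG pathways from 3 to 33 for tumor against normal (3 without wild-type normal 3, 33 without wild-type normal 2) and from 21 to 54 for knockout against wild type (21 without knockout tumor 2, 27 without wild-type tumor 2). Without knockout tumor 2 the muscle list, at 3.95, was no longer called. Without knockout normal 3, comparisons that need that group have no value. Knockout against wild type then becomes knockout tumor against wild-type tumor, and tumor against normal becomes that comparison within wild type. This also holds where both libraries with muscle transcripts are left out. Leaving out both wild-type libraries numbered 2 gave 12 lists for the difference of tumor effects, and 39 and 17 KEGG pathways for tumor against normal and knockout against wild type. Leaving out both libraries with muscle transcripts gave 26 KEGG pathways for knockout against wild type. At the authors' adjusted p of 0.05, their tables held 134, 176, 195 and 88 genes for the pairs named knockout 3, wild type 1, wild type 2 and wild type 3.

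Directions reversed as follows. Without both wild-type libraries numbered 2, Mup7 was at 1.53 within wild type and 0.40 in tumor against normal, Hsd3b5 at 0.19 and the male-biased list at 0.43. Without both muscle libraries, Mylpf was at -1.36, Ckm at -3.50, Actn3 at -2.91, Acta1 at -6.00 and the muscle list at -3.30, where knockout tumor 3 alone is left for the genotype and wild-type tumor 1, with Acta1 at 29.7 CPM, stays on the other side. Nfib within knockout was at 0.0210 with library totals, 0.0168 with FPKM plus 1, filtered or not, and 0.0183 with FPKM plus 0.1, and in knockout normal against wild-type normal at -0.15 with library totals, -0.0708 with the block across genotypes, -0.12 with FPKM plus 1, filtered or not, and -0.13 with FPKM plus 0.1. The median of all genes lay at -0.20 with library totals in that comparison (-0.0297 with TMM), at -0.15 within wild type (0.00297) and at 0.23 in the difference of tumor effects (0.0145), and at -0.13, -0.11 and 0.16 with FPKM plus 1 and -0.16, -0.14 and 0.20 with FPKM plus 0.1. Nags in tumor against normal was at 0.0077 with the block within genotype.

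With 1 library left out, values ran from -0.0346 to 1.71 for Ifit1 and from -0.0915 to 1.10 for the interferon list in knockout against wild-type tumor, from -7.61 to 0.31 for Hsd3b5, from -7.86 to 0.41 for Mup7, from -0.22 to 0.0408 for Nags and from -2.86 to 0.37 for the male-biased list in tumor against normal, from -8.86 to 1.46 for Mup7 within wild type, and from -0.0239 to 0.10 for Nfib in knockout normal against wild-type normal. Depth limits single genes at low counts, and 4481 of 21878 genes had 0 counts in every library, a number that was not traced to depth.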

Other observations

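All tests in this part were planned, except that the lists described here and their values with a library left out were picked after the result was seen. Beyond the lists described above, camera called glutamine and ammonia metabolism higher over both tissues in the libraries labelled knockout (14 of 20 genes, median 0.54, adjusted p 6.13e-04), where DESeq2 called Got1, and the xenobiotic P450 and conjugation genes (18 of 23, median 0.51, adjusted p 2.46e-05), each with adjusted p = 0.408 with an estimated correlation. The xenobiotic median was 0.29 without wild-type normal 2, 0.78 without wild-type tumor 3 and 0.81 without wild-type normal 3.

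Some calls over both tissues were lost when 1 library was left out. Acute phase genes were higher in 18 of 21 (median 0.56, adjusted p 1.16e-04, and adjusted p = 0.408 with an estimated correlation), and the call was lost without knockout normal 3 (median 0.13, camera adjusted p 0.104). That last fit compares knockout tumor with wild-type tumor only. Without wild-type normal 2 their median was 0.36 and without knockout tumor 2 it was 0.87. Pericentral genes were higher in 18 of 20 (median 0.44, adjusted p 2.13e-04, and adjusted p = 0.550 with an estimated correlation), and the call was lost without wild-type tumor 2 (median 0.14, camera adjusted p 0.0746), whose mean deviation over the list was -2.97. Their median was 0.76 without wild-type tumor 1, 0.65 without wild-type tumor 3 and 0.22 without wild-type normal 2. MAPK feedback genes were lower in 17 of 19 (median -0.38, adjusted p 0.00227, and adjusted p = 0.460 with an estimated correlation), and the call was lost without wild-type tumor 1 (median -0.37, camera adjusted p 0.107). The 4 genes of the nuclear factor I family, Nfib among them, had a median of 0.28 and were not called (adjusted p 0.133).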
